A study of Danio rerio with 30 samples.

How the data were processed

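The data were RNA-seq read counts per gene from 30 libraries of zebrafish haematopoietic stem and progenitor cells. The cells were sorted by low GFP from larvae carrying a GFP transgene under the promoter of itga2b, the gene of the platelet integrin CD41. Embryos were either wild type or heterozygous for a mutation of rps14, which encodes a protein of the small ribosomal subunit. Per the labels' protocols, some embryos were exposed to 1 µg/mL phenylhydrazine (Phz), a compound that destroys red blood cells, from 24 to 48 hours post fertilization. All were then kept for 4 days in 20 µM imiquimod, an agonist of the toll-like receptor TLR7, or in its solvent DMSO. Per the labels' protocols, genotypes came from tail clips, embryos of a group were pooled before sorting, and full-length cDNA libraries were made by Smart-seq2. The labels number the replicates within a group and do not say whether each number is a separate pool of embryos, so p-values measure the spread between these samples, part of which may be technical.

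The values used were the whole-number counts per gene that the authors deposited, not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.1.0, SAMtools 1.9, featureCounts from Subread 2.0.0 and DESeq2, with the genome build GRCz11. The annotation release, the use of strand and the filter that set which genes the table holds were not given in the sources used here. The table held 20631 genes with a lowest total of 25 counts over the 30 libraries. Each of its 30 columns matched 1 sample and 0 columns were left unmapped. Counts per gene summed to between 5703056 and 15238153 per library (median 6894464). Smart-seq2 reads carry no molecular identifiers, so the depth gives an upper limit on the number of molecules counted. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart.

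Gene symbols came from a reference table of gene identifiers, which matched 19528 identifiers. That table writes many zebrafish genes in the capital letters of their human counterparts (RPS14, CCNG1), and symbols are printed as it gives them. Of the 19930 genes tested, 18909 had a symbol and 2551 shared theirs with another gene, mostly duplicated copies. RNF14 and CAPRIN1 are among the latter, and values of near-identical copies are uncertain where reads could be split between them. Gene positions were not used here.

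Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM normalization (factors 0.896 to 1.07), a low-count filter by group (filterByExpr), estimateDisp, and the robust quasi-likelihood test (glmQLFit, glmQLFTest) in 1 model with a coefficient for each of the 8 groups. The common dispersion of 0.674 corresponds to a biological coefficient of variation of 0.821, and the median prior had 10.2 degrees of freedom. In this model 16 contrasts were tested: genotype, Phz and imiquimod effects within single conditions, each averaged over the other 2 factors, and 4 interactions. The design, the alternatives and the gene lists were fixed before the data were examined. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Fold changes are log2 values with the standard error taken from the quasi-likelihood F statistic, and levels are CPM, a gene's share of its library's counts scaled to a common total, computed from the deposited counts.

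Named genes followed a fixed rule. RPS14, TLR7 and itga2b were always examined. Among called genes with a mean log2 CPM of at least 1, an informative symbol and the same sign in at least 3 of the component differences of an averaged contrast, up to 12 per direction with the largest change could be named. Where fewer than 5 passed, the 5 named genes of smallest p were given as values, and up to 4 members of smallest p were named per list. Any other gene named was chosen after its values were seen.

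The 29 gene lists covered ribosomal proteins, ribosome biogenesis, mitochondrial transcripts, nuclear oxidative phosphorylation, glycolysis, growth arrest and apoptosis genes with some of DNA repair, interferon-stimulated genes, NF-kB and proinflammatory cytokine genes, JAK-STAT signalling, the toll-like receptor pathway, antigen presentation, aryl hydrocarbon receptor targets, immediate-early genes, heat shock proteins, the unfolded protein and integrated stress response, NRF2 and antioxidant genes, and the cell cycle. They also covered markers of stem and progenitor, erythroid, thrombocyte, macrophage, neutrophil, lymphoid, endothelial, kidney tubule, skeletal muscle, epidermal, neural and retinal, and liver and exocrine pancreas cells. Lists overlapped by at most 5 genes. They were tested with camera from limma 3.58.1 on the same model, with an inter-gene correlation preset to 0.01, and Benjamini-Hochberg adjusted over all 464 list tests. Of these, 122 passed, and 1 passed with a correlation estimated from the data, that of the growth arrest and apoptosis genes for genotype averaged over conditions. Single members were counted over all genes tested and adjusted over the list alone. As a check with libraries as the unit, the mean log2 CPM of each list per library was compared with permuted labels, 348 tests per family, and 0 passed after adjustment. Single-condition comparisons had only 10 to 126 possible splits of their libraries, so their tests could hardly pass this adjustment. They were adjusted together with the averaged effects. The 0 therefore cannot decide whether a list moved.

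Library measures were compared by two-sided permutation tests with 100000 resamples (12 tests, adjusted together). Within groups, 43 pairs of libraries were compared by a chi-square statistic over genes, which was at least 21.3 per gene, so no library was counted as a duplicate. The replicate numbers were checked for pairing across groups. The library numbers in the labels were divided into 3 runs, S1 to S6, S7 to S29 and S30 to S33, the second joining S7 to S24 with S26 to S29. No number is skipped at the boundaries of these runs, and the one between S29 and S30 was set after the values were seen. The runs were examined as a possible batch after the data were seen, since the labels do not state that they mark one. Each run held wild-type and heterozygous libraries. A term for these runs could be fitted because S1 to S6 and S30 to S33 each shared groups with S7 to S29. S30 to S33 held Phz DMSO libraries alone, and S1 to S6 held no such library. For Phz DMSO the term therefore rests on S26 to S29, 1 wild-type and 3 heterozygous libraries. No other group has numbers from S26 on, so Phz in DMSO cannot be told from a batch that starts there. The same holds for imiquimod against DMSO after Phz, since all Phz imiquimod libraries have numbers up to S24. The run term joins S7 to S24 with S26 to S29 and cannot separate them.

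The steps were tested on simulated counts for the 19930 genes with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. In the simulation of genotype averaged, the ribosomal protein genes were also changed by a log2 of -0.5, and calls of these counted as true. For genotype averaged, edgeR recovered 48% of the changes of log2 1 and 85% of those of log2 2, with 17 of 181 calls false. For heterozygotes against wild type under Phz in DMSO it recovered 9% and 51%, with 1 of 61 calls false, so this contrast would miss most changes of log2 1. The other single-condition contrasts were not simulated. DESeq2 1.42.0 recovered 58% and 94% for genotype averaged with 76 of 266 calls false, and called 18 genes where none had been changed, against 0 for edgeR and 0 for voom.

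Alternatives were DESeq2, limma voom with library quality weights, DESeq2 size factors inside edgeR, no low-count filter, the replicate number as a block, the libraries S1 to S6 left out, an estimated inter-gene correlation, and each library left out in turn. Added after the data were seen were a term for the runs of library numbers, the libraries S30 to S33 left out, the permuted list scores, and the same checks on the library measures. Figures were drawn with matplotlib 3.10.9. Raw reads were not analysed here. Some genes are not reported here.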

Results

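Gene expression was measured by RNA-seq in haematopoietic stem and progenitor cells, the GFP-low fraction of an itga2b:GFP transgenic line, sorted from zebrafish larvae at 6 days post fertilization. The larvae were wild type or heterozygous for rps14, the gene of a small ribosomal subunit protein whose human counterpart is often lost from 1 chromosome in a subtype of myelodysplastic syndrome. Each genotype was studied with and without earlier phenylhydrazine (Phz), which destroys red blood cells, and with imiquimod, a TLR7 agonist, or DMSO. The question was how imiquimod acts on stressed heterozygous cells. Wild-type groups held 3 unstressed DMSO, 4 unstressed imiquimod, 3 Phz DMSO and 4 Phz imiquimod libraries. Heterozygous groups held 4, 3, 5 and 4 in the same order, giving 14 wild-type and 16 heterozygous libraries.

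Total counts ranged from 5703056 to 15238153 per library, and 14789 to 20109 genes had at least 1 count. The most abundant gene, ENSDARG00000080337, took 5.81 to 9.43% of counts. Genotype moved the share of the 50 most abundant genes, 15 of which encode ribosomal proteins. This share averaged 29.7 to 30.7% in the wild-type groups and 27 to 27.6% in the heterozygous groups. The difference of -3.04 points gave a permutation p of 1e-05, the smallest the resamples can give (adjusted p = 0.00012 over 12 tests). Phz libraries held 1591800 more counts on average (permutation p = 0.00105, adjusted p = 0.0063). Imiquimod libraries had 1375 more genes detected (permutation p = 0.00998, adjusted p = 0.0399). The number of tests past the threshold, 3 here, was 1 without S1 to S6 and 1 without replicate 1 or 3 of heterozygous unstressed imiquimod. The share of mitochondrial transcripts differed by 0.20 points with genotype (permutation p = 0.21), 0.181 with Phz (permutation p = 0.23) and -0.202 with imiquimod (permutation p = 0.186). The first 4 principal components held 11.2, 7.34, 5.28 and 4.75% of the variance.

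RPS14 (ENSDARG00000036629), the mutated gene, was examined first. Its level was 610 ± 118 CPM (SD, n = 3) in wild-type unstressed DMSO libraries, 501 ± 159 (n = 4) with imiquimod, 542 ± 89.4 (n = 3) after Phz and 537 ± 131 (n = 4) after Phz with imiquimod. The heterozygous groups held 238 ± 40.3 (n = 4), 189 ± 87.8 (n = 3), 273 ± 50.7 (n = 5) and 230 ± 79.1 CPM (n = 4) in the same order. All 16 heterozygous libraries (94.8 to 340 CPM) lay below all 14 wild-type libraries (348 to 688 CPM). Averaged over the conditions, RPS14 fell by 1.25 on the log2 scale (standard error 0.14, edgeR adjusted p = 2.4e-06). TLR7, the receptor of imiquimod, averaged 0.757 CPM, ranked 17650 by level and had 0 counts in 16 of the 30 libraries. The gene itga2b, whose promoter drives the GFP transgene, averaged 9.16 ± 9.51 CPM (SD, n = 30; 0.271 to 35.8 CPM). TLR7 and itga2b each passed the threshold in 0 of the 16 contrasts by edgeR's test.

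Averaged over the conditions, the growth arrest and apoptosis list was higher in heterozygous cells. CCNG1 (cyclin G1) rose by a log2 fold change of 1.65 ± 0.11 (SE, edgeR adjusted p = 2.9e-12), from 401 ± 62.0 CPM (SD, n = 14) in wild-type to 1258 ± 304 CPM (n = 16) in heterozygous libraries. Its heterozygous range of 566 to 1803 CPM lay above the wild-type range of 311 to 504 CPM. From the same list, rps27l rose by 0.89 ± 0.12 (adjusted p = 5.5e-05) and the ubiquitin ligase gene mdm2 by 0.79 ± 0.12 (adjusted p = 0.0005). Of the 28 tested growth arrest and apoptosis genes, 22 had positive fold changes (median 0.20). The list passed camera's test (adjusted p = 1.3e-08) and kept its call with an estimated correlation (adjusted p = 0.024).

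**Figure D1:**
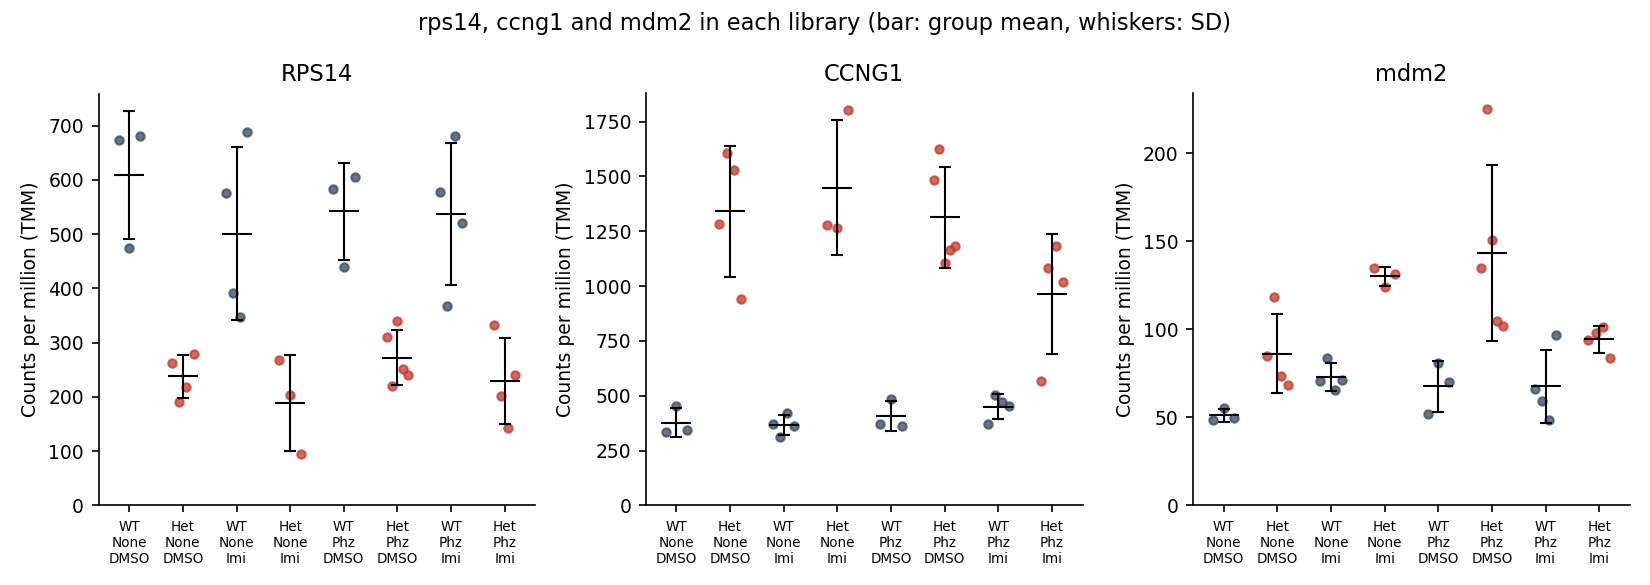
CPM of RPS14, CCNG1 and mdm2 in each of the 30 libraries, by group, with the mean and SD of each group. RPS14 is lower in all 16 heterozygous libraries (at most 340 CPM) than in the wild-type ones (at least 348 CPM), and CCNG1 is higher (at least 566 against at most 504 CPM).

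Ribosomal protein genes moved together with genotype. All 76 tested members had negative fold changes (median -0.46), 31 fell over all genes and 65 fell adjusted over the list alone. Among the strongest beside RPS14 were RPS9 (-0.87 ± 0.12, adjusted p = 6.1e-05) and RPL17 (-0.71 ± 0.12). RPS9 averaged 2271 ± 373 CPM in wild-type and 1279 ± 354 CPM in heterozygous libraries (SD, n = 14 and 16). The list's adjusted p was 1.8e-79 with the preset correlation, and adjusted p = 0.14 with an estimated correlation. The mean list score per library differed by -0.47 (permutation p = 0.0005, adjusted p = 0.174 over 348 tests), and by -0.48 within runs of library numbers. The 46 ribosome biogenesis genes went the other way, with 40 positive, a median of 0.13 and 0 past the threshold over the list alone (adjusted p = 0.00027, adjusted p = 0.85 with an estimated correlation). This did not extend to every ribosome assembly gene. RSL24D1 (-0.73) and nop53 (-0.72), factors of large subunit assembly outside this list, fell and were called over all genes.

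In all, edgeR called 87 genes for genotype averaged over conditions, 15 higher and 72 lower in heterozygotes, with 1789 at an unadjusted p under 0.05. DESeq2 called 259 and voom 136. Among the other named genes that rose were RNF14 (2.24 ± 0.41, a ubiquitin ligase that shares its symbol with another gene), OGFRL1 (2.01 ± 0.48), plin6 (1.99 ± 0.42, a lipid droplet protein), DLAT (0.59 ± 0.14, a pyruvate dehydrogenase subunit), GART (0.57 ± 0.13, a purine synthesis enzyme), hmgb1b (0.49 ± 0.11) and eif4ebp1 (0.40 ± 0.08, an inhibitor of translation initiation). Genes that fell included RBL2 (-0.99 ± 0.21, a retinoblastoma family protein), JAKMIP1 (-0.93 ± 0.22), RPL22L1 (-0.88 ± 0.15), rbm48 (-0.85 ± 0.19), ALDH1L1 (-0.79 ± 0.14, a folate enzyme), RSL24D1 (-0.73 ± 0.12) and nop53 (-0.72 ± 0.10), both factors of large subunit assembly, and CAPRIN1 (-0.67 ± 0.12, an RNA-binding protein that shares its symbol). The chaperone HSP90AB1 fell by 0.39 (SE 0.07, adjusted p = 0.0022). The calls of OGFRL1, JAKMIP1, DLAT, GART and hmgb1b ended when any of 18 to 24 single libraries was left out, and that of plin6 with S1 to S6 left out, with the run term and with voom. The count of 87 became 56 without replicate 1 of wild-type unstressed DMSO, 49 without replicate 3 of heterozygous unstressed imiquimod and 47 without replicate 3 of wild-type Phz DMSO.

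**Figure D2:**
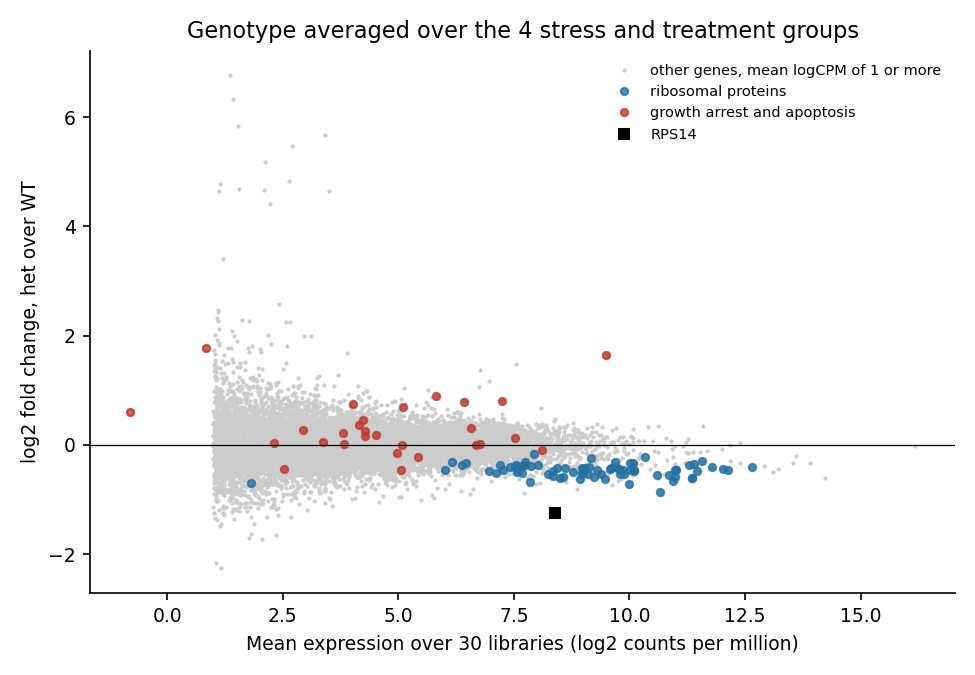
Log2 fold change of heterozygous over wild-type libraries, averaged over the 4 conditions, against mean log2 CPM for each gene, with ribosomal protein genes in blue, growth arrest and apoptosis genes in red and RPS14 as a black square. Other genes are drawn from a mean log2 CPM of 1. All 76 tested ribosomal protein genes lie below 0, and among the red points CCNG1 lies at 1.65 and the weakly expressed PHLDA3, picked out after its value was seen, at 1.78.

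Further lists passed camera's test with the preset correlation in the same contrast. Of 25 neutrophil genes 24 were negative (1 positive, median -0.37) and 3 fell adjusted over the list alone, among them LECT2 (-0.64 ± 0.15), a leukocyte chemotaxin. The adjusted p was 8.1e-10, and adjusted p = 0.54 with an estimated correlation. Cell cycle genes had 43 of 50 positive (median 0.24), and 4 rose adjusted over the list alone, including KIF23 (0.73 ± 0.19) and TTK (0.79 ± 0.21), which act in mitosis. Their adjusted p was 1.3e-07, and adjusted p = 0.51 with an estimated correlation. Toll-like receptor pathway genes (median -0.17, adjusted p = 0.014), JAK-STAT genes (median -0.13, adjusted p = 0.035), nuclear oxidative phosphorylation (median 0.11, adjusted p = 0.0059) and mitochondrial transcripts (median 0.16, adjusted p = 0.045) passed with smaller shifts, and none of these passed with an estimated correlation (adjusted p = 0.51 for the first pair, adjusted p = 0.86 for the others). Each of these 4 calls also ended without at least 1 single library. Genes of stem and progenitor cells (39 tested, median -0.02, adjusted p = 0.79), thrombocytes (29, median 0.01, adjusted p = 0.79), lymphoid cells (28, median -0.13, adjusted p = 0.16) and macrophages (33, median 0.17, adjusted p = 0.21) did not pass. Neither did glycolysis (32, median -0.06, adjusted p = 0.2), antigen presentation (26, median -0.01, adjusted p = 0.84), interferon-stimulated genes (31, 15 positive, adjusted p = 0.97), aryl hydrocarbon receptor targets (11, median 0.11, adjusted p = 0.67) or neural and retinal genes (37, median 0.18, adjusted p = 0.9).

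Genes of the exocrine pancreas, a tissue outside the sorted population, were high in part of the libraries. Of 34 liver and exocrine pancreas genes 25 were positive with genotype (median 2.59), and 18 rose and 1 fell adjusted over the list alone, such as the proteases ctrb.3 (6.34 ± 1.51) and ela3l (5.47 ± 1.33). The adjusted p was 5.9e-05, and adjusted p = 0.85 with an estimated correlation. The summed level of the enzyme genes reached 8099 CPM, 0.780% of counts, in replicate 1 of heterozygous Phz DMSO, and 5 of the 6 libraries with over 50 CPM of prss1, a trypsin gene chosen after its values were seen, were heterozygous. This tally depends on the cut. Just under it lay the wild-type library S21 (49.2 CPM), the heterozygous S18 (42.6 CPM) and the wild-type S1 (34.5 CPM).

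**Figure D3:**
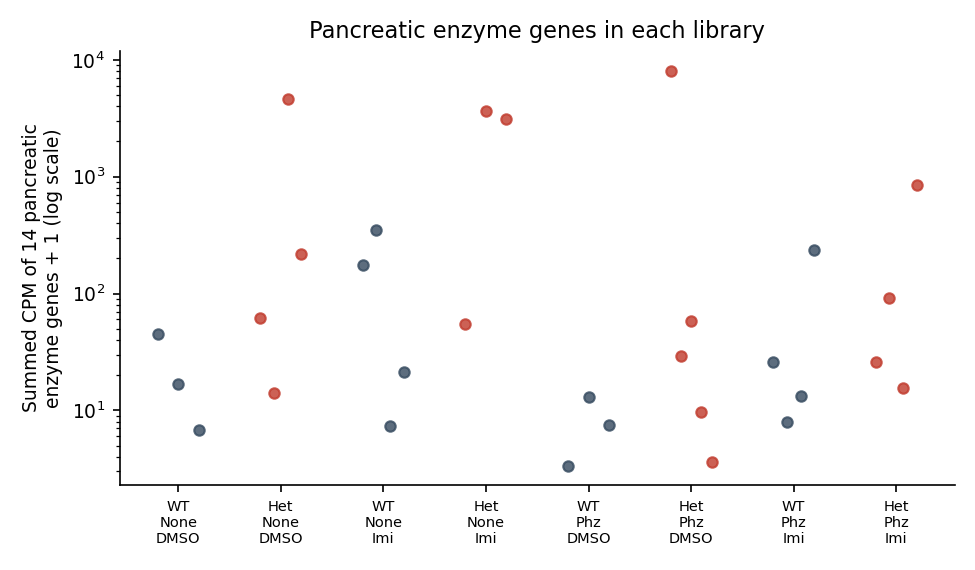
Summed CPM (plus 1, log axis) of 14 exocrine pancreas enzyme genes in each library, heterozygous in red and wild type in blue-grey. The highest value, 8099 CPM, belongs to a heterozygous Phz DMSO library.

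Heterozygotes were then compared with wild type within single conditions. In unstressed DMSO larvae, CCNG1 was the 1 gene that passed (1.83 ± 0.22, edgeR adjusted p = 4e-05), with 1628 genes at an unadjusted p under 0.05. DESeq2 called 54 and voom 1. RPS14 was at -1.36 ± 0.28 (adjusted p = 0.16) and the actin gene actb2 at -0.89 ± 0.17 (adjusted p = 0.15). All 76 ribosomal protein genes were negative (median -0.55) and 24 fell adjusted over the list alone (adjusted p = 2.4e-28, adjusted p = 0.72 with an estimated correlation). Ribosome biogenesis genes were at a median of 0.29, with 42 of 46 positive and 4 that rose adjusted over the list alone, such as RCL1 (0.86 ± 0.23; adjusted p = 6.8e-07, adjusted p = 0.75 with an estimated correlation). Neutrophil genes were at -0.76 (adjusted p = 4.7e-09, adjusted p = 0.59 with an estimated correlation) and NF-kB genes at -0.75 (adjusted p = 0.0034, adjusted p = 0.86 with an estimated correlation; median -0.68 with the run term), the latter call ending without replicate 3 of the wild-type group (median -0.28). Erythroid genes were at 0.41 with 37 of 45 positive (adjusted p = 9.4e-06, adjusted p = 0.85 with an estimated correlation), and their call ended without replicate 2 of wild-type unstressed DMSO (median 0.23). The count of 1 gene became 3 and 7 without replicates 1 and 2 of the wild-type group.

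After Phz in DMSO, the condition of the stressed heterozygote, CCNG1 was again the 1 gene called (1.69 ± 0.22, edgeR adjusted p = 0.00011; 1560 genes at an unadjusted p under 0.05). DESeq2 called 70 and voom 4. The growth arrest and apoptosis genes rps27l (1.06 ± 0.23) and mdm2 (1.08 ± 0.25, adjusted p = 0.47) did not pass over all genes, while 4 of the list's 28 members rose adjusted over the list alone. The list had 25 positive members and a median of 0.51 (adjusted p = 2.8e-05, adjusted p = 0.091 with an estimated correlation; median 0.27 with the run term). Erythroid genes lay lower in heterozygotes: 41 of 45 were negative (4 positive, median -0.59), with alas2, the first enzyme of haem synthesis, at -1.94 ± 0.69 and hemgn at -1.25 ± 0.48. Their adjusted p was 3.2e-11, and adjusted p = 0.67 with an estimated correlation, and 0 members passed adjusted over the list alone. The erythroid median was -0.33 with the run term. Ribosomal protein genes were at -0.34 (3 fell adjusted over the list alone, adjusted p = 7.3e-16, adjusted p = 0.85 with an estimated correlation).

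After Phz with imiquimod, edgeR called 0 genes (699 at an unadjusted p under 0.05), against 4 by DESeq2 and 10 by voom. CCNG1 was at 1.1 ± 0.20 (adjusted p = 0.07) and RPS14 at -1.23 ± 0.26 (adjusted p = 0.57). DESeq2 and voom called both of these genes, and CCNG1 was also called without the low-count filter, with the replicate block and with the run term. The growth arrest and apoptosis list had 19 of 28 positive and a median of 0.27 (adjusted p = 0.00014, adjusted p = 0.11 with an estimated correlation). Ribosomal protein genes were at -0.45, with 12 that fell adjusted over the list alone (adjusted p = 8.9e-34, adjusted p = 0.59 with an estimated correlation). Cell cycle genes were at 0.34, 43 of 50 positive (adjusted p = 2.2e-08, adjusted p = 0.51 with an estimated correlation). Endothelial genes were at 0.33 (18 of 26 positive, adjusted p = 0.031, adjusted p = 0.79 with an estimated correlation).

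The effect of the earlier Phz exposure was examined in DMSO-treated larvae of each genotype. In wild type, erythroid genes were higher after Phz: 41 of 45 were positive (median 0.80), and 6 rose adjusted over the list alone, including the membrane protein gene epb41b (1.13 ± 0.29), znfl2a (1.15 ± 0.34) and klf17 (2.30 ± 0.72), an erythroid transcription factor. The list's adjusted p was 1.2e-16, and adjusted p = 0.51 with an estimated correlation, with a median of 0.58 under the run term. Over all genes edgeR called 0 (2138 at an unadjusted p under 0.05; DESeq2 126, voom 0), the smallest p values being those of mief2 (-3.22 ± 0.72) and clk4a (0.96 ± 0.22; adjusted p = 0.30). In heterozygotes edgeR called 0 genes (1394 at an unadjusted p under 0.05; DESeq2 17, voom 0), led by EIF2S1 (-0.82 ± 0.19, a translation initiation factor) and GFM2 (1.72 ± 0.41; adjusted p = 0.57). Their NF-kB genes were at a median of 0.69 with 31 of 39 positive (adjusted p = 0.00098, adjusted p = 0.86 with an estimated correlation; median 0.99 with the run term), a call that ended without replicate 1 of the Phz group (median 0.67). The interaction of genotype with Phz had 0 genes by edgeR (1514 at an unadjusted p under 0.05; DESeq2 57, voom 1). Its erythroid median was -1.16, with 4 of 45 positive and 4 that fell adjusted over the list alone (adjusted p = 1.1e-15, adjusted p = 0.51 with an estimated correlation; median -0.94 with the run term).

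Averaged over genotype and treatment, Phz changed 4 genes, 2 in each direction (edgeR; 2462 at an unadjusted p under 0.05; DESeq2 167, voom 56). The mitochondrial import receptor gene tomm20a rose by 0.67 ± 0.12 (adjusted p = 0.030) and ahnak, a large scaffold protein gene, fell by 0.75 (SE 0.13, adjusted p = 0.029). In wild type, ahnak averaged 136 CPM in DMSO and 179 with imiquimod without Phz, against 71.1 and 71 CPM after it. PHEX, present in few Phz libraries, was at -5.17 ± 0.97 (adjusted p = 0.038), and the fourth was zgc:56095, named here after its values were seen. The ferritin gene fth1a (0.48 ± 0.10) and the erythroid gene znfl2a (0.79 ± 0.16) missed the threshold (adjusted p = 0.053 for each). Erythroid genes had 40 of 45 positive (median 0.37, 2 rose adjusted over the list alone, adjusted p = 1.5e-13, adjusted p = 0.53 with an estimated correlation). Of 32 NRF2 and antioxidant genes 26 were positive (median 0.20), and 6 rose adjusted over the list alone, including fth1a, gpx1a (0.35 ± 0.08), PRDX3 (0.49 ± 0.12) and SOD2 (0.37 ± 0.11), which detoxify iron or oxygen species. Their adjusted p was 1.6e-05, and adjusted p = 0.21 with an estimated correlation, with a median of 0.21 under the run term. Ribosome biogenesis genes had 41 of 46 positive (median 0.20), with 10 that rose adjusted over the list alone, such as WDR12 (0.47 ± 0.11) and GNL3 (0.38 ± 0.09; adjusted p = 3.2e-11, adjusted p = 0.51 with an estimated correlation). Heat shock proteins were at 0.38 (17 of 22 positive, adjusted p = 0.0014, adjusted p = 0.23 with an estimated correlation). The count of 4 genes fell to 0 without any 1 of 7 libraries, replicates 1 and 2 of heterozygous unstressed imiquimod, replicates 2 and 4 of wild-type unstressed imiquimod, replicate 4 of wild-type Phz imiquimod, replicate 2 of heterozygous Phz imiquimod and replicate 4 of heterozygous Phz DMSO, and it was at most 8 without any other. The call of ahnak ended with S1 to S6 left out, and the calls of all 4 genes ended with the replicate number as a block.

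Imiquimod was compared with DMSO in 4 settings. In unstressed wild type, genes of the respiratory chain lay lower with imiquimod. All 13 mitochondrial transcripts were negative (median -0.74) and 9 fell adjusted over the list alone, including MT-CO2 (-0.74 ± 0.16) and MT-ND6 (-1.45 ± 0.33). MT-CO2 averaged 5223 ± 1214 CPM (SD, n = 3) in DMSO and 3129 ± 279 CPM (n = 4) with imiquimod. Of 94 nuclear genes of oxidative phosphorylation 8 were positive (median -0.54), and 28 fell adjusted over the list alone, among them cox6b2 (-1.03 ± 0.21) and COX7A2 (-1.20 ± 0.27), subunits of cytochrome c oxidase. The adjusted p was 3e-18 for the mitochondrial and 8.6e-36 for the nuclear list, and adjusted p = 0.091 and adjusted p = 0.055 with an estimated correlation. Ribosomal protein genes were at -0.53 (9 fell adjusted over the list alone, adjusted p = 7.6e-24, adjusted p = 0.79 with an estimated correlation). Over all genes edgeR called 0 (1407 at an unadjusted p under 0.05; DESeq2 77, voom 0), led by SPOPL (1.64 ± 0.29, adjusted p = 0.065) and the splicing protein gene SNRPF (-1.35 ± 0.26, adjusted p = 0.15). The count was 10 without replicate 2 of the DMSO group and 1 without replicate 1 of the imiquimod group.

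In unstressed heterozygotes imiquimod gave 0 genes by edgeR (876 at an unadjusted p under 0.05; DESeq2 12, voom 0). The splicing factor gene SF3A2 was at -0.92 and the tetraspanin gene CD81 at 0.76. Nuclear oxidative phosphorylation genes were again lower, with 12 of 94 positive (median -0.40, adjusted p = 4e-18, adjusted p = 0.23 with an estimated correlation). Mitochondrial transcripts were at 0.25 (12 of 13 positive, adjusted p = 0.031, adjusted p = 0.86 with an estimated correlation). The interaction of genotype with imiquimod for this list had a median of 1.01, all 13 positive and 8 past the threshold over the list alone (adjusted p = 2.3e-17, adjusted p = 0.091 with an estimated correlation). For that interaction edgeR called 0 genes (1046 at an unadjusted p under 0.05; DESeq2 7, voom 0), MT-CO2 (1.13 ± 0.23, adjusted p = 0.52) having the smallest p. Ribosomal protein genes were at -0.38 in heterozygotes (adjusted p = 5e-22, adjusted p = 0.79 with an estimated correlation), and their call ended without replicate 3 of the imiquimod group (median -0.09). Macrophage genes were at 0.41 (29 of 33 positive, adjusted p = 0.018, adjusted p = 0.86 with an estimated correlation), and at -0.08 without the same library.

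In stressed wild type, immune lists were higher with imiquimod. Interferon-stimulated genes had 25 of 31 positive (median 0.83, adjusted p = 0.011, adjusted p = 0.51 with an estimated correlation). NF-kB and proinflammatory cytokine genes had 35 of 39 positive (median 0.69, adjusted p = 0.00017, adjusted p = 0.85 with an estimated correlation), and macrophage genes 29 of 33 (median 0.72, adjusted p = 2.1e-05, adjusted p = 0.79 with an estimated correlation). No member of these lists passed adjusted over the list alone. The DMSO group mixed libraries of different number runs. With the run term the medians were 0.39, -0.24 and 0.30 in the same order, so the sign of the NF-kB difference turned with this term. Only 1 DMSO library, S26, shared a run with imiquimod libraries of stressed wild type, the run that joins S7 to S24 with S26 to S29. The NF-kB score (mean log2 CPM) of S26, at 4.76, lay between those of S19, S20 and S21 (5.38, 5.50 and 4.29). All these DMSO libraries have numbers from S26 on and the imiquimod ones up to S24, so a batch between them cannot be told from imiquimod. Without replicate 2 of the DMSO group the interferon and NF-kB calls ended (medians 0.62 and 0.42). Kidney tubule genes (median 0.84, adjusted p = 0.023) and epidermal genes (median 0.83, adjusted p = 0.0096) were also higher, with adjusted p = 0.79 and adjusted p = 0.83 with an estimated correlation. Other tissue lists had medians as high or higher without passing, namely skeletal muscle (2.86), liver and exocrine pancreas (1.68), neural and retinal (0.99) and endothelial genes (0.92). Over all genes edgeR called 0 (1818 at an unadjusted p under 0.05; DESeq2 81, voom 3), and OGFRL1 (5.90 ± 1.24, adjusted p = 0.38) had the smallest p, at 0.185 ± 0.213 CPM in DMSO (SD, n = 3) and 12.1 ± 3.8 CPM with imiquimod (n = 4).

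In stressed heterozygotes, the setting of the series' question, imiquimod gave 0 genes by edgeR (858 at an unadjusted p under 0.05; DESeq2 13, voom 0). The DMSO libraries of this setting had numbers from S27 on and the imiquimod ones up to S24. Imiquimod can therefore not be told here from a batch that follows the numbers. The smallest p values were those of TYRP1 (6.57 ± 1.39, adjusted p = 0.76), a melanin synthesis gene, ENTPD6 (6.31 ± 1.39) and RNF213 (1.2 ± 0.28), an interferon-responsive ubiquitin ligase. TYRP1 and ENTPD6 had few counts in the DMSO libraries. Erythroid genes had 35 of 45 positive (median 0.27, adjusted p = 0.0038, adjusted p = 0.86 with an estimated correlation; median 0.41 with the run term), and alas2 averaged 15.7 ± 10.9 CPM (SD, n = 5) in DMSO and 50.9 ± 37.4 CPM (n = 4) with imiquimod. The erythroid call ended without any 1 of replicates 1 and 4 of the imiquimod group and 1 and 2 of the DMSO group. Interferon-stimulated genes were at 0.07 (19 of 31 positive, adjusted p = 0.16), NF-kB genes at 0.02 (adjusted p = 0.2) and stem and progenitor genes at -0.12 (adjusted p = 0.094). Macrophage genes were at 0.24 (26 of 33 positive, adjusted p = 0.048, adjusted p = 0.86 with an estimated correlation), at 0.03 with the run term and at -0.13 without S30 to S33. Whether imiquimod acted differently in stressed heterozygotes than in stressed wild type was tested as an interaction. It had 0 genes by edgeR (1091 at an unadjusted p under 0.05; DESeq2 36, voom 0). Its erythroid median was 0.47, with 39 of 45 positive (adjusted p = 2.2e-06, adjusted p = 0.85 with an estimated correlation; median 0.25 with the run term), and that of interferon-stimulated genes was -0.45 (adjusted p = 0.21).

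Averaged over the 4 settings, imiquimod changed 1 gene, si:ch211-136a14.2 (1.63, edgeR adjusted p = 0.0016), which is named here after its values were seen (1789 genes at an unadjusted p under 0.05; DESeq2 54, voom 4). OGFRL1 was at 2.68 ± 0.49 (adjusted p = 0.052), the granulin gene grna at 0.87 ± 0.18, the progenitor surface gene cd34 at -0.69 ± 0.14 (adjusted p = 0.14 for each) and the chemokine gene ccl35.2 at 1.96 ± 0.42. DESeq2 called these 4 genes, and voom called OGFRL1 and cd34. In DMSO cd34 averaged 159 ± 21 CPM (SD, n = 3) in unstressed wild type, against 94.5 ± 22 CPM (n = 4) with imiquimod. In the list of stem and progenitor genes cd34 and FLI1 (-0.52 ± 0.14) fell adjusted over the list alone, at a list median of -0.08 (adjusted p = 0.031, adjusted p = 0.53 with an estimated correlation). Nuclear oxidative phosphorylation genes had 7 of 94 positive (median -0.20, adjusted p = 8.1e-21, adjusted p = 0.17 with an estimated correlation) and ribosomal protein genes 1 of 76 (median -0.24, 11 fell adjusted over the list alone, adjusted p = 7.4e-30, adjusted p = 0.68 with an estimated correlation). Among NF-kB genes 29 of 39 were positive, and the chemokine ccl19a.1 (3.63 ± 0.87), tnfaip2b (2.40 ± 0.58) and RIPK2 (0.92 ± 0.30) rose adjusted over the list alone (median 0.18, adjusted p = 0.0053, adjusted p = 0.86 with an estimated correlation), with a median of -0.07 under the run term. The count of 1 gene was 0 without replicate 3 of heterozygous unstressed imiquimod and 5 without replicate 3 of heterozygous unstressed DMSO. It was 3 without replicate 2 of wild-type Phz imiquimod, and 2 without replicate 1 of heterozygous unstressed imiquimod, replicate 1 of heterozygous unstressed DMSO or replicate 3 of wild-type unstressed DMSO.

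The imiquimod effect with Phz was also set against that without it, averaged over genotype. With Phz, imiquimod libraries up to S24 were compared with DMSO libraries from S26 on, so this effect cannot be told from a batch that starts there. The imiquimod medians of nuclear oxidative phosphorylation genes were -0.54 in wild type and -0.40 in heterozygotes without Phz, and 0.12 and 0.10 with it. The difference was positive in 87 of 94 (median 0.53). Over all genes 1 rose (atp5if1a, an inhibitor of the mitochondrial ATP synthase), and 35 rose and 1 fell adjusted over the list alone, such as cox7b (1.53 ± 0.31) and COX5B (0.93 ± 0.20). The adjusted p was 2e-26, and adjusted p = 0.091 with an estimated correlation, with a median of 0.68 under the run term. In all, edgeR called 7 genes (1764 at an unadjusted p under 0.05; DESeq2 102, voom 10). The actin-binding protein gene pfn1 (1.07 ± 0.19, adjusted p = 0.035), the co-chaperone gene ST13 (1.64 ± 0.32) and atp5if1a (1.2 ± 0.24, adjusted p = 0.048) had positive interactions, and the translation elongation factor gene eef2b (-0.78 ± 0.15) and the cytokine receptor kinase gene jak3 (-1.94 ± 0.37) negative ones. In wild type, pfn1 averaged 3299.9 CPM in DMSO and 2274 with imiquimod without Phz, against 2353 and 3521 CPM after Phz. The means of jak3 were 18.7 and 41.0 CPM without Phz and 34.6 and 13 CPM after it. The remaining 2 genes were si:dkeyp-116a7.2 and si:ch73-308b14.1, named after their values were seen. The count was 1 to 9 when single libraries were left out, and the calls of ST13, atp5if1a, eef2b and jak3 each ended without any 1 of at least 20 libraries.

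Whether imiquimod moved stressed heterozygotes back toward stressed wild type was examined across 19930 genes, which are not independent replicates. The fold changes of genotype after Phz and of imiquimod in stressed heterozygotes had a Pearson r of -0.378 and a Spearman rho of -0.277, and 59% of genes had opposite signs. Both comparisons use the heterozygous Phz DMSO libraries, which alone gives a negative value. In 50 simulations without any effect, r averaged -0.399 (-0.422 to -0.366). The covariance was -0.804, against -0.660 in the simulations (-0.708 to -0.583), a difference of -0.145. The simulations drew each gene independently from 1 mean, without the difference between S26 to S29 and S30 to S33. The gap in covariance can therefore not be read as an effect of imiquimod. With the shared libraries divided between the comparisons in 10 ways, r averaged 0.040 (-0.004 to 0.107) and the covariance 0.128. The 3 divisions with only libraries of S27 to S29 on the genotype side gave 0.089 to 0.107, and the others -0.004 to 0.025. Among called genes, 1 for genotype (CCNG1) and 0 for imiquimod, 0 were shared.

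The 8 Phz DMSO libraries differed from each other by the library numbers in the labels. NF-kB scores (mean log2 CPM) were 4.70 to 5.15 in S26 to S29 and 2.36 to 2.94 in S30 to S33, a difference of 2.26 (exact permutation p = 0.0286 over 70 splits, adjusted p = 0.0592 over 29 lists). The cytokine gene il1b, named after its values were seen, ranged from 842 to 1379 CPM in the first 4 and from 0.836 to 5.55 CPM in the last 4. In the other groups il1b was at 24.6 to 219 CPM in S1 to S6 and at 58.6 to 1258 CPM in S7 to S24. The set that lay apart from the other libraries was thus S30 to S33. The shift was broad: 14 of the 29 lists had the same lowest p. Among them, score differences were 2.25 for liver and exocrine pancreas genes, 2.07 for immediate-early genes and 1.43 for aryl hydrocarbon receptor targets. They were 0.95 for the unfolded protein and integrated stress response, 0.51 for glycolysis, -0.68 for erythroid and -0.47 for mitochondrial genes. The mitochondrial share was 1.45 to 1.87% of counts in S26 to S29 and 2.22 to 2.63% in S30 to S33. The boundary was chosen after the values were seen. Each set held both genotypes, so the heterozygous minus wild-type difference could be taken within them. For NF-kB genes it was 0.44 pooled and 0.18 and -0.45 within the sets. For erythroid genes it was -0.57 pooled and -0.26 and -0.53 within them.

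**Figure D4:**
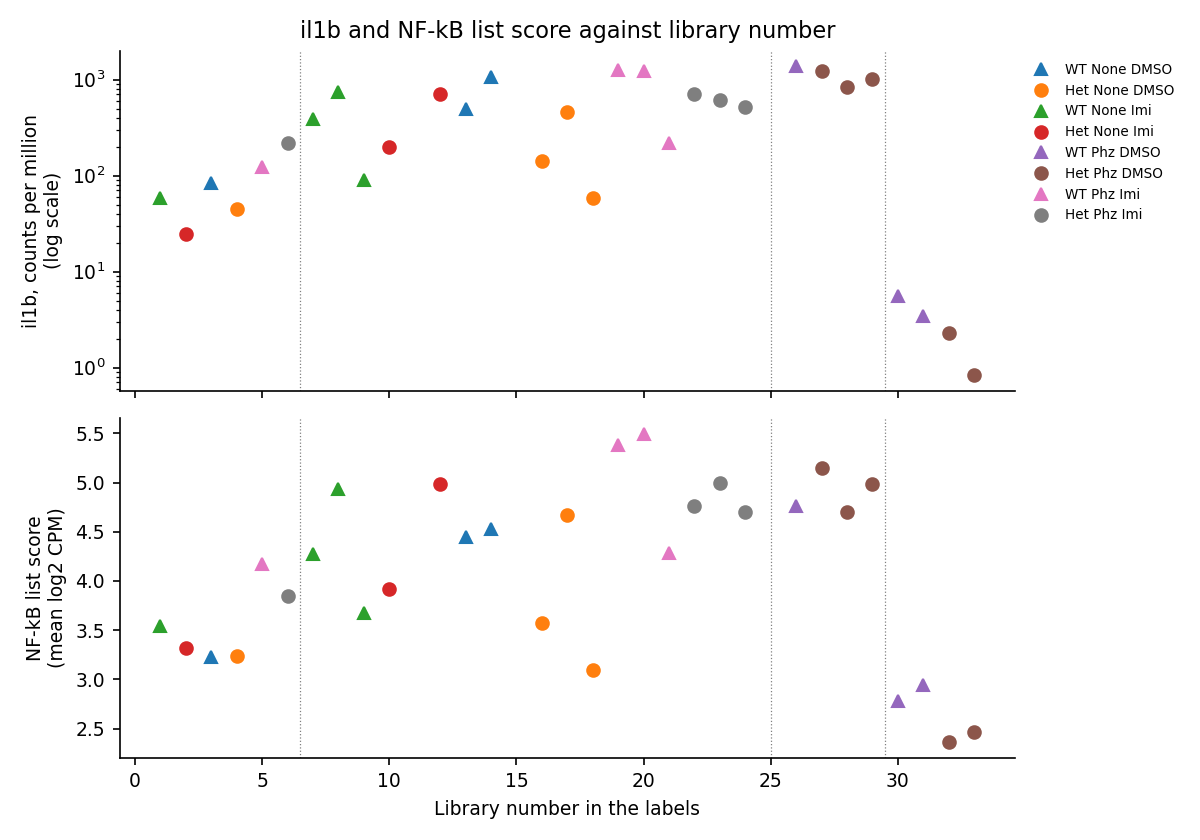
CPM of il1b (above, log axis) and mean log2 CPM of the NF-kB list (below) in each library against its library number, by group. The Phz DMSO libraries S26 to S29 lie at 842 to 1379 CPM and at scores of 4.70 to 5.15, and S30 to S33 at 0.836 to 5.55 CPM and at 2.36 to 2.94.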

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

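The comparisons of the library-number runs and every test of an explanation in this part were chosen after the results were seen, while the interactions and the search for libraries that stand apart were planned.

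Of 175 tests for a library far from the others of its group, 4 found one, and chance gives about 1 in 20 (5%). Groups of 3 libraries were not tested. These were wild-type unstressed DMSO, wild-type Phz DMSO and heterozygous unstressed imiquimod. Replicate 3 of wild-type unstressed imiquimod had a total of 6557319 counts, against 5703056 to 5840749 in the others. The ribosomal protein score was 8.75 in replicate 2 of wild-type Phz imiquimod, against 9.53 to 9.66. The score of aryl hydrocarbon receptor targets was 3.87 in replicate 3 of the same group, against 1.65 to 2.0. The JAK-STAT score was 4.51 in replicate 4 of heterozygous Phz DMSO, against 4.93 to 4.97.

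The Phz effect in DMSO differed between genotypes for 8 lists by camera with the preset correlation, and for none of them with an estimated correlation. The median interactions (heterozygous minus wild type) were -1.16 for erythroid, 1.13 for NF-kB, 0.62 for neutrophil, 0.56 for immediate-early (0.28 without S30 to S33, where camera's direction turned), 0.35 for unfolded protein and integrated stress response, 0.22 for ribosomal protein, -0.28 for ribosome biogenesis and -2.15 for skeletal muscle genes (-0.80 without replicate 4 of heterozygous unstressed DMSO, which ended the call). The imiquimod effect after Phz differed for 5 lists with the preset correlation and for none of them with an estimated one. The medians were -0.68 for NF-kB (0.060 with the run term), 0.47 for erythroid, -0.42 for macrophage, -0.33 for neutrophil and -0.44 for epidermal genes. The imiquimod effect without Phz differed for 10 lists with the preset correlation, again for none with an estimated one. These were mitochondrial transcripts (1.01), NF-kB (0.69), macrophage (0.62), neutrophil (0.42), nuclear oxidative phosphorylation (0.24), ribosome biogenesis (-0.19), cell cycle (-0.30), erythroid (-0.42), kidney tubule (-2.03) and skeletal muscle genes (-2.19, and -0.59 without the same replicate 4, which ended the call).

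The imiquimod effect differed between stressed and unstressed larvae for 7 genes, and for 6 lists with the preset correlation, none of which passed with an estimated one. The list medians were 0.53 for nuclear oxidative phosphorylation, 0.38 for ribosomal protein, 0.34 for immediate-early (-0.28 without S30 to S33, -0.15 with the run term), 0.49 for interferon-stimulated, 0.26 for macrophage and 0.66 for epidermal genes. The gene values were 1.64 for ST13, 1.2 for atp5if1a, 1.07 for pfn1, -0.78 for eef2b, -1.94 for jak3, -1.57 for si:ch73-308b14.1 and -2.51 for si:dkeyp-116a7.2.

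The inflammatory lists of the interactions that involve Phz rest on Phz DMSO libraries that differ by library number. S26 to S29 were higher than S30 to S33 for 34 of 39 NF-kB genes (median 1.76). The set that lay apart was S30 to S33, with NF-kB scores of 2.36 to 2.94. Scores were 3.23 to 4.17 in S1 to S6 and 3.09 to 5.50 in S7 to S29. Genotype was argued against as the whole source, since the wild-type library S26 exceeded the mean of the wild-type libraries S30 and S31 by 1.9 in NF-kB score. Depth was argued against because mean totals had a ratio of 1.000. A different share of neutrophils or macrophages in the sort stays open, although the GFP gate should remove mature cells of these kinds. Their own genes were higher in S26 to S29 by medians of 0.651 and 1.08, less than the NF-kB genes. But lyz was at 5493 CPM or more even in S30 to S33, a level that would hide a small added share, and the macrophage genes csf1ra (2.12) and marco (2.67) rose more than the NF-kB median. A batch effect that follows the library numbers stays open and may account for the pattern: in the other 6 groups S1 to S6 lay lower than S7 to S24 by a mean NF-kB score difference of -0.926, in the same direction in each group. The labels do not say what the numbers mark, and a difference between the embryo pools was not tested.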

How the results depend on the processing

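The library-number term, the libraries S30 to S33 left out and the alternatives for library measures were chosen after the data were seen, and the cause of a change was not tested unless stated. In the order of the report, DESeq2 called 54, 70 and 4 genes for heterozygotes against wild type (unstressed DMSO, Phz DMSO, Phz imiquimod), 126 and 17 for Phz (wild type, heterozygotes), and 77, 12, 81 and 13 for imiquimod (unstressed wild type and heterozygotes, stressed wild type and heterozygotes). It called 259 for genotype, 167 for Phz and 54 for imiquimod averaged, and 57, 36, 7 and 102 for the interactions of genotype with Phz, with imiquimod after Phz, with imiquimod without Phz, and of Phz with imiquimod. In the self-test DESeq2 also made more false calls than edgeR. Voom with quality weights called 4 genes for heterozygotes against wild type after Phz, 10 after Phz with imiquimod, 3 for imiquimod in stressed wild type, 136, 56 and 4 for the averaged effects and 1 for genotype by Phz. DESeq2 size factors gave 3 for Phz by imiquimod, and no low-count filter gave 4 there and 1 for heterozygotes against wild type after Phz with imiquimod. With an estimated correlation, 1 of 122 list calls remained.

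The numbers of the replicates were entered as a block. They did not pair the samples: same-numbered libraries correlated at a mean of 0.014 (-0.094 to 0.183), 8 of 94 pairs exceeded 0.1, and 10 of 30 libraries correlated best with their own number. With the block, counts were 1 for heterozygotes against wild type after Phz with imiquimod, 0 for Phz averaged, 2 for imiquimod averaged and 11 for Phz by imiquimod.

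Leaving out S1 to S6 gave 2 genes for heterozygotes against wild type in unstressed DMSO, 1 for Phz in wild type, 1 for imiquimod in stressed wild type, 2 for Phz averaged, 2 for imiquimod averaged, 1 for genotype by Phz and 2 for Phz by imiquimod, and 1 library measure past the threshold. Leaving out S30 to S33 left 1 wild-type Phz DMSO library, assumed to vary like the other groups. It gave 89 genes for heterozygotes against wild type after Phz, 115 for Phz in wild type, 94 for imiquimod in stressed wild type, 148, 126 and 33 for genotype, Phz and imiquimod averaged, and 59, 40 and 47 for genotype by Phz, genotype by imiquimod after Phz and Phz by imiquimod, which rest on that library. The run term gave 3 for unstressed DMSO, 1 after Phz with imiquimod, 3 for Phz in heterozygotes, 3 for imiquimod in unstressed wild type, 189 for genotype averaged, 29 for Phz averaged and 4 for Phz by imiquimod.

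List directions turned in few settings. Without S30 to S33, immediate-early genes were at 0.34 for Phz in wild type, -0.41 and -0.16 for imiquimod in stressed wild type and heterozygotes, and -0.28 for Phz by imiquimod. NF-kB genes were at -0.18 for imiquimod in stressed wild type and -0.10 averaged, erythroid genes at 0.51 in stressed wild type and macrophage genes at -0.13 in stressed heterozygotes. Camera's direction, though not the median, turned for neutrophil genes with Phz averaged (-0.14) and immediate-early genes for genotype by Phz (0.28). With the run term the values were 0.37, -0.32, -0.10 and -0.15 for immediate-early genes in the first 4 comparisons, -0.24 and -0.074 for NF-kB, 0.16 for erythroid genes in stressed wild type, 0.060 for NF-kB in genotype by imiquimod after Phz, and -0.16 for macrophage genes with Phz in wild type, where only camera's direction turned. Without replicate 3 of heterozygous unstressed imiquimod, macrophage genes there were at -0.082, and at 0.61 without replicate 1.

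The correlation of -0.378 between genotype and imiquimod changes was -0.256 at a mean log2 CPM of at least 3, -0.196 with the run term, and 0.040 with the shared libraries divided, which removes what the shared libraries add. It ranged from -0.464 to -0.290 when single libraries were left out.

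Leaving out single libraries gave 47 to 117 genes for genotype, 0 to 8 for Phz and 0 to 5 for imiquimod averaged, and 1 to 9 for Phz by imiquimod. Heterozygotes against wild type ranged from 1 to 7 in unstressed DMSO, 1 to 2 after Phz and 0 to 1 after Phz with imiquimod. Phz ranged from 0 to 1 in wild type and 0 to 0 in heterozygotes, and imiquimod from 0 to 10 and 0 to 1 unstressed and 0 to 1 in each stressed genotype. Genotype by Phz ranged from 0 to 2 and genotype by imiquimod from 0 to 0 with and without Phz, list calls from 92 to 148, and library measures past the threshold from 1 to 3. CCNG1 averaged over conditions stayed called without any of the 30 libraries (1.61 to 1.70). Of 103 single genes tested with the run term 93 kept their side of the threshold, 5 lost and 5 gained a call. Of 122 list calls 83 held with the run term and 96 with the block. The comparison of heterozygotes with wild type after Phz detected 9% of changes of log2 1 in the self-test.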

Other observations

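The tests of explanations for ribosomal protein and pancreas genes were chosen after the results were seen, while the counts over other splits of the samples were planned.

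The sorted cells carried strong myeloid expression along with progenitor regulators. The genes of this paragraph were chosen after their values were seen. The lysozyme gene lyz averaged 10643 CPM (3733 to 28615 CPM, n = 30) and was the gene of rank 6 by mean level, and npsn, a neutrophil protease gene, averaged 2089 CPM at rank 41. The myeloid transcription factor genes CEBPA and SPI1 averaged 1198 and 493 CPM. Among regulators of stem and progenitor cells, MYB averaged 674 CPM (433 to 1107), LMO2 315 CPM and RUNX1 16.7 CPM. MYD88, the adaptor downstream of most toll-like receptors, averaged 53.7 CPM, against 0.757 CPM for TLR7. In wild-type unstressed DMSO libraries lyz stood at 17162 ± 10299 CPM (SD, n = 3) and in the heterozygous ones at 8360 ± 5323 CPM (n = 4).

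Skeletal muscle genes, from a tissue outside the sorted population, varied with single libraries. In unstressed DMSO larvae 23 of 26 were higher in heterozygotes (median 2.17, adjusted p = 0.0025 by camera, adjusted p = 0.85 with an estimated correlation), and the median was 0.65 without replicate 4 of the heterozygous group. After Phz with imiquimod 3 of 26 were positive (median -1.95, adjusted p = 0.0012, adjusted p = 0.85 with an estimated correlation), and the median was 0.14 without replicate 4 of the wild-type group.

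The lower ribosomal protein expression in heterozygotes (median -0.46 over 76 genes) was weighed against technical explanations. High abundance as the whole source was argued against: of 1000 gene lists matched on mean level, the lowest median was -0.126. The 50 most abundant other genes had a median of -0.21, so abundance may account for a part. A batch effect along the library numbers was argued against by a median of -0.468 with a term for the runs, and 1 deviating library by a median no closer to 0 than -0.385 when each was left out. What stays open is an effect of genotype, which may lower ribosomal protein transcripts as a group, and a different mix of cells in the sorted fraction, which was not tested.

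Pancreatic enzyme genes above 50 CPM of prss1 occurred in 6 libraries, 5 heterozygous and 1 wild type, and the next highest library, at 49.2 CPM, was wild type. RNA from pancreas cells is a candidate source: the ratio of ctrb.1 to prss1 differed by at most 1.5-fold among these libraries (0.446 to 0.668) while prss1 ranged over 17.8-fold. The GFP gate should remove such cells, so free RNA or carried-over cells may be involved, which was not tested. A link to genotype also stays open, with a permutation p of 0.0340 for the list score (adjusted p = 0.564 within the library-number runs, where the permutation p was 0.0491).

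Other splits of the same samples were used to ask whether chance could give as many genes. For genotype averaged, chance was excluded at this level: 1 of 100 splits, the real one, reached the real count of 87, and the highest other had 3. For Phz averaged only the real split reached its count (1 of 100, 4 genes against at most 2). The Phz by imiquimod interaction was alike (1 of 100, 7 against 1). With 100 splits a share cannot be lower, and the shares were not adjusted over the comparisons, so chance was not clearly excluded for either. Both also use the Phz DMSO libraries, whose numbers start at S26, so these splits cannot tell Phz from a batch that starts there. For imiquimod averaged 3 of 100 splits reached the real count of 1 gene, the real one among them. Other splits thus gave as many genes, and the shares were not adjusted over the comparisons, so chance was not clearly excluded there. For heterozygotes against wild type in unstressed DMSO chance was not excluded, 8 of 35 splits reaching the real 1 gene (highest other 16), nor after Phz, with 12 of 56 splits (1 gene; highest other 141). That split of 141 genes set S30, S32 and S33 against S26 to S29 and S31, largely along the library-number runs. It and the next ones, with 89, 77 and 73 genes, point to a structure of these samples, and with the run term as an alternative the real comparison had 1 gene. With a real count of 0, each of the splits reached it: 35 of 35 after Phz with imiquimod (highest other 0), 35 of 35 for imiquimod in unstressed wild type (0), 35 of 35 in unstressed heterozygotes (0), 35 of 35 in stressed wild type (1) and 100 of 100 in stressed heterozygotes (1). The same was true of Phz in heterozygotes (100 of 100; highest other 54), of genotype by Phz (100 of 100; 140), and of genotype by imiquimod with Phz (100 of 100; 12) and without it (100 of 100; 5). The splits with 54 and 140 genes also point to a structure of the samples, the first setting S32 and S33 against the other 3 Phz libraries. Phz in wild type had 10 splits, too few for a share under 0.05 (10 of 10; real 0, highest other 3).

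Counts of lists, here adjusted within each comparison, were less distinct from other splits. For genotype averaged 13 of 100 splits had as many as the real 11 lists (highest other 17), so chance was not excluded, and the same held for Phz averaged (20 of 100; 11 lists, highest other 16) and imiquimod averaged (10 of 100; 13, highest other 17). For heterozygotes against wild type the splits reaching the real number were 3 of 35 in unstressed DMSO (13 lists; highest other 13), 48 of 56 after Phz (5; 18) and 24 of 35 after Phz with imiquimod (6; 13). For imiquimod they were 27 of 35 in unstressed wild type (4; 15), 6 of 35 in unstressed heterozygotes (11; 14), 19 of 35 in stressed wild type (8; 15) and 93 of 100 in stressed heterozygotes (3; 17). For Phz in heterozygotes they were 75 of 100 (5; 17), for genotype by Phz 54 of 100 (8; 17), for genotype by imiquimod 99 of 100 with Phz (1; 16) and 10 of 100 without it (11; 13), and for Phz by imiquimod 60 of 100 (6; 18). Chance was excluded for none of these. Phz in wild type had 10 splits, too few for a share under 0.05 (4 of 10; 8 lists, highest other 14). Camera's calls with the preset correlation are therefore given above as descriptions of the lists.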
